A study of Mus musculus with 12 samples.

How the data were processed

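RNA was sequenced from the cortex of SNAP25 bacTRAP mice at postnatal day 21, per the labels. In a bacTRAP line, a ribosomal protein fused to enhanced green fluorescent protein (GFP) is made in chosen cells, here under the control of the neuronal gene Snap25, so that ribosomes of those cells and the mRNA on them can be pulled down with antibodies against GFP (translating ribosome affinity purification, TRAP). Per the labels, the 12 libraries form 4 groups of 3. WCH is the whole cortex homogenate, and TRAP is the immunoprecipitate from it. SNF is the synaptic band of a sucrose and percoll gradient before immunoprecipitation, and SynapTRAP is the immunoprecipitate from that band. The replicates are labelled as separate samples, but nothing in the labels says that they came from separate animals, so the p-values measure only the spread between samples.

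Per the labels, cDNA was made with a NuGEN kit. Per the submitters' processing notes, Bowtie2, STAR, HTSeq and edgeR were used. Their versions, the genome build, the annotation, the strand setting and the meaning of the replicate numbers are not given in the sources used here. Reads of overlapping or antisense genes were therefore not separable. Rpl10a and the other cytosolic ribosomal protein genes, which share sequence with many pseudogenes, are reported as uncertain. Other genes were not checked for close copies, though 14.4% to 28.9% of the reads of a library did not align to a unique place. The authors deposited 1 integer count per gene and library for 29879 genes, followed by 5 summary lines for reads that were counted for no gene. These 5 lines held 19.3% to 58.3% of all reads of a library and were left out of the gene counts. Per the file headers, the authors also deposited 3 tables of selected genes with log2 fold changes, unadjusted p-values and false discovery rates. The filter behind these tables is not given in the sources used here.

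Gene counts per library were 4368881 to 14335089, and counts outside the mitochondrial genome were 1819853 to 7115176. Intervals of shares given for single libraries are 95% Wilson intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. Between replicates of a group, the chi-square statistic per gene was 11.9 to 349 where counting error alone gives about 1, and the Spearman correlation across genes was 0.937 to 0.985. On this measure, counting error alone does not account for the spread between replicates. The statistic used raw counts scaled by total gene counts, mitochondrial RNA included, and is a mean over genes. It therefore also carries differences in mitochondrial share and the weight of abundant genes. It does not show how large counting error was for genes of few counts.

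Symbols for 28758 identifiers came from GENCODE M21 (GRCm38), 11 came from the authors' tables and 1110 identifiers had none. Coordinates are those of GENCODE M21 on GRCm38, counted from 1. Of 3875 genes for which the authors' tables give a chromosome, 3865 had the same chromosome in that annotation.

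All 12 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with group means, trimmed mean of M-values (TMM) scaling and the default expression filter, which kept 13404 genes. Each of 5 contrasts was tested with the robust quasi-likelihood test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were TRAP against WCH, SNF against WCH, SynapTRAP against SNF, SynapTRAP against TRAP, and the difference between both immunoprecipitation effects (SynapTRAP minus SNF, less TRAP minus WCH). Counts-per-million values (CPM) were computed here with the same scaling, and each log2 fold change is given with its standard error (SE) from that fit. Every p in the text that carries no other name is an adjusted p from this edgeR test.

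Before the data were examined, 30 gene lists were fixed. They hold markers of neurons, excitatory and inhibitory neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelial and mural cells, fibroblasts and meninges, blood, choroid plexus and ependyma, hippocampus and striatum. The others are dendritically localized mRNAs, postsynaptic density, presynaptic, ion channel, cytoskeleton, ribosomal protein, translation factor, endoplasmic reticulum, oxidative phosphorylation, mitochondrially encoded, glycolysis, proteasome, cholesterol synthesis, immediate early, transcription factor and chromatin genes, and nuclear noncoding RNAs. Each list was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the 30 lists of a contrast. List medians are given relative to the median of all tested genes. Beside each list call stands the adjusted p of the same test with the correlation estimated per list. No list call of any contrast held with an estimated correlation. The calls were 16, 18, 13, 16 and 13 in the order of contrasts above, and the smallest of those p in each contrast were 0.0783, 0.319, 0.117, 0.163 and 0.0544. A further test, fry, asks whether the genes of a list move one way on balance and does not compare them with other genes. It also called 11, 16, 1, 16 and 1 of these lists. The statements on lists rest on the preset correlation and on the counts of called members.

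The rule for named genes was also fixed then. For each pairwise contrast it took the 8 highest and the 8 lowest log2 fold changes among called genes with a mean of at least 10 CPM and no overlap between the libraries of both groups, leaving out accession-like names and mitochondrially encoded genes. It added up to 3 members with the smallest p of each list described, and Snap25, Rpl10a, Camk2a, Gfap and Mbp as checks. For the difference between immunoprecipitation effects it took the 5 highest and the 5 lowest. GFP was added after the count files were seen to have an entry for it, and any other gene named outside the rule is said to be so.

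Same-numbered replicates were checked for shared deviations from their group means. The correlation across genes was 0.218 to 0.378 between SynapTRAP and SNF and 0.104 to 0.144 between SynapTRAP and TRAP, so the numbers were treated as pairing those groups. It was −0.015 to 0.063 between WCH and TRAP and 0.065 to 0.165 between WCH and SNF, which were not treated as paired. Every same-numbered pair of WCH and SNF libraries correlated better than their pairings with other numbers, as in the groups treated as paired. WCH and SNF were set apart by the size of the correlation alone, so a pairing there is not excluded. The pairing comes from the data alone, and the fit with the replicate number as a block was an alternative. The other alternatives were DESeq2 1.42.0, relative log expression (RLE) factors, total counts as the scaling, no expression filter, a filter of at least 5 CPM in 3 libraries, the mitochondrially encoded genes left out, only the groups compared, and each library left out in turn. After the data were seen, 2 more were added, which are only the groups compared together with the block, and the TRAP and SynapTRAP libraries numbered 3 left out together.

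The test was run on simulated data with 13404 genes, of which 100 changed by a log2 of 1 and 100 by a log2 of 2. In the order of contrasts above, it called 28%, 18%, 24%, 22% and 5% of the smaller changes and 90%, 73%, 68%, 73% and 50% of the larger ones. False calls made up 4.8%, 11.7%, 2.1%, 1% and 3.5% of all calls. In 8 further simulations, run after the first, they made up 5.7%, 5.1%, 3.9%, 5.2% and 6.3% of all calls together and 8%, 6.7%, 7.4%, 8.2% and 14.3% in the worst simulation. The false share can therefore exceed 5%. The bound first set for this test, over 50% of the larger changes in every contrast, was missed by the difference between immunoprecipitation effects. In the further simulations, 48% to 67% of the larger changes were called there. Its estimates were close to the simulated changes (median error 0.073), so the bound was afterwards kept for the 4 pairwise contrasts alone.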

Results

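Gene expression was measured by RNA sequencing in 12 libraries of mouse cortex, 3 each of homogenate (WCH), ribosomes immunoprecipitated from it (TRAP), the synaptic band of a density gradient (SNF) and ribosomes immunoprecipitated from that band (SynapTRAP). Gene counts were 7650524, 9567146 and 9082512 in WCH replicates 1 to 3 and 6503955, 4368881 and 6378765 in TRAP. They were 14335089, 11637339 and 13579503 in SNF and 10084335, 8938193 and 9762434 in SynapTRAP. Between 14595 and 17458 genes were detected per library. The groups differed most in mitochondrial RNA. The mitochondrially encoded ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 38.8% ± 8.91 (SD, n = 3) of the gene counts in WCH, 3.61% ± 2.36 in TRAP, 81.0% ± 2.51 in SNF and 37.9% ± 21.6 in SynapTRAP. The SynapTRAP libraries ranged widely, with 33.1%, 19.2% and 61.6% (95% Wilson intervals at most 0.0663 percentage points wide). The SNF libraries therefore held only 1819853 to 2111322 counts outside the mitochondrial genome, against 5190228 in WCH, 5509842 in TRAP and 5766387 in SynapTRAP on average. Reads outside annotated genes made up 23.2% ± 4.89 (SD, n = 3) of all reads in WCH, 16.3% ± 0.561 in TRAP, 3.90% ± 2.37 in SNF and 11.2% ± 5.81 in SynapTRAP. Mitochondrial reads in the total lower these shares.

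**Figure D1:**
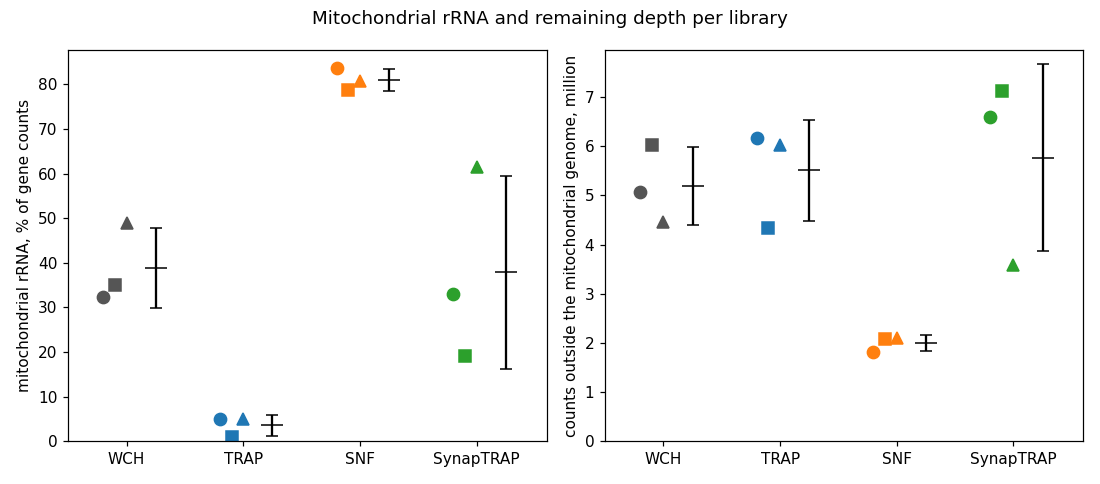
Share of gene counts from the mitochondrial ribosomal RNAs (vertical axis, percent) in each library of the 4 groups, with circle, square and triangle for replicates 1, 2 and 3 and bars for the mean ± SD of 3 libraries. The SNF libraries average 81.0%, the TRAP libraries 3.61%, and the SynapTRAP libraries spread from 19.2% to 61.6%.

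The GFP transgene and markers of neurons and 3 kinds of glia were compared between the preparations, and not every marker list split the groups in the same way. GFP mRNA, which encodes the ribosome tag, averaged 5.99 ± 1.30 CPM (SD, n = 3) in WCH, 32.8 ± 19.3 in TRAP, 3.25 ± 0.43 in SNF and 9.05 ± 1.36 in SynapTRAP. Its raw counts were low, at 66 to 94, 241 to 643, 10 to 14 and 51 to 133 per library in these groups. The mean of 20 neuron markers exceeded that of 20 astrocyte markers by 2.26 ± 0.13 log2 CPM (SD, n = 3) in WCH and by 3.72 ± 0.33 in TRAP, but only by 0.48 ± 0.37 in SNF and 0.64 ± 0.44 in SynapTRAP. Against 20 oligodendrocyte markers, the difference was 1.78 ± 0.21, 3.51 ± 0.43, 0.69 ± 0.29 and 0.94 ± 0.16 in the same order. Against 20 microglia markers, it was 4.89 ± 0.12, 6.55 ± 0.28, 2.68 ± 0.51 and 3.25 ± 0.38. Every TRAP library lay above every WCH library on the 3 scores, and every SNF and SynapTRAP library lay below every WCH library. Single TRAP libraries stood apart on other lists. The mean of 16 endothelial markers was 2.5 log2 CPM in TRAP replicate 2, against 0.22 and 0.53 in the other TRAP libraries and 0.60 to 0.81 in WCH (1 of 16 called higher in TRAP than in WCH, relative list median 0.94, camera adjusted p = 0.177; adjusted p = 0.771 with an estimated correlation). Without TRAP replicate 2 the relative list median was −0.13. Mural cell markers averaged 1.80 in TRAP replicate 2, 0.72 and 0.44 in the other TRAP libraries and 1.02 to 1.24 in WCH (1 of 10 called lower, camera adjusted p = 0.743; adjusted p = 0.927 with an estimated correlation). In TRAP replicate 3, fibroblast and meninges markers (3.14) and oligodendrocyte precursor markers (3.96) lay above every WCH library (at most 2.70 and 3.68).

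**Figure D2:**
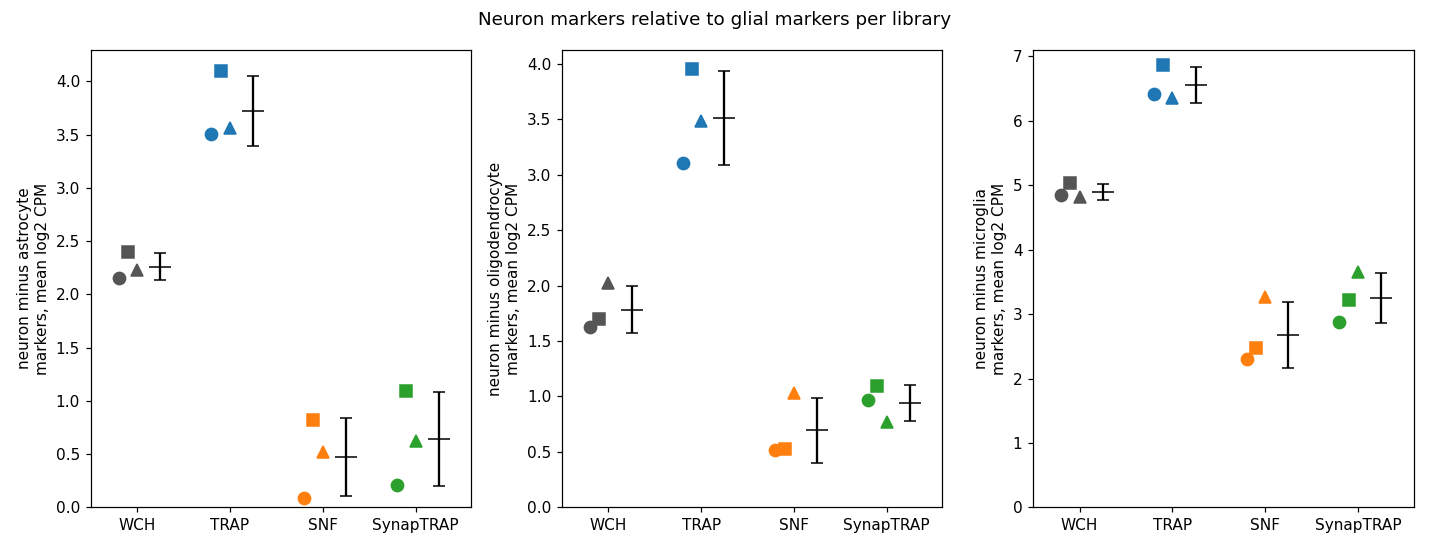
Mean log2 CPM of neuron markers minus that of astrocyte (left), oligodendrocyte (middle) and microglia markers (right) in each library of the 4 groups, with circle, square and triangle for replicates 1, 2 and 3 and bars for the mean ± SD of 3 libraries. The TRAP libraries lie highest, at means of 3.72, 3.51 and 6.55, and the SNF and SynapTRAP libraries lie lowest.

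TRAP was compared with WCH to ask which mRNAs were on the tagged neuronal ribosomes of the whole cortex. In TRAP, 49 of 74 oxidative phosphorylation, 11 of 16 glycolysis, 16 of 31 proteasome and 25 of 51 cytoskeleton genes were higher. Lower were 12 of 20 oligodendrocyte, 9 of 20 astrocyte and 7 of 20 microglia markers and 6 of 7 mitochondrially encoded mRNAs. The calls of these lists did not hold with an estimated correlation (adjusted p = 0.0783 to 0.341 with an estimated correlation). Kalrn (ENSMUSG00000061751, a protein-coding gene on chromosome 16, 33969073 to 34573532), which encodes a guanine nucleotide exchange factor of dendritic spines, rose from 202 ± 6.44 CPM in WCH to 1370 ± 877 in TRAP (SD, n = 3; log2 fold change 2.76, SE 0.323, edgeR adjusted p = 1.95e-05; 2.14 without TRAP replicate 3). GFP itself rose by a log2 fold change of 2.45 (SE 0.329, edgeR adjusted p = 7.24e-05; 1.86 without the TRAP and SynapTRAP libraries numbered 3). Tspan2, a tetraspanin of oligodendrocytes (ENSMUSG00000027858, chromosome 3, 102734529 to 102801513), was lower at 29.8 ± 11 CPM in TRAP against 205 ± 19.9 in WCH (log2 fold change −2.78, SE 0.282, edgeR adjusted p = 3.76e-06).

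Of 74 nuclear-encoded oxidative phosphorylation genes, 49 rose in TRAP (55 adjusted over the list alone), among them the complex III subunits Uqcr11 (log2 fold change 1.79) and Uqcr10 (1.75) and the complex I subunit Ndufa13 (1.75). The list median was 1.06 above that of all genes (camera adjusted p = 2e-24; adjusted p = 0.0783 with an estimated correlation). Of 16 glycolysis genes, 11 rose (14 adjusted over the list alone), including hexokinase Hk1 (1.44), Gpi1 (1.21) and Pfkl (1.19), with a relative list median of 1.12 (camera adjusted p = 6.11e-08; adjusted p = 0.341 with an estimated correlation). Of 31 proteasome genes, 16 rose (17 adjusted over the list alone), such as Psmb3 (1.26) and Psmb4 (1.16), with a relative list median of 0.66 (camera adjusted p = 1.74e-08; adjusted p = 0.341 with an estimated correlation). Of 51 microtubule and actin cytoskeleton genes, 25 rose (27 adjusted over the list alone), among them the dynein heavy chain Dync1h1 (2.44) and the tubulins Tubb4b (1.73) and Tuba1b (1.43), with a relative list median of 0.72 (camera adjusted p = 2.94e-08; adjusted p = 0.341 with an estimated correlation). The cytoskeleton list averaged 7.57, 6.94 and 8.12 log2 CPM in TRAP replicates 1 to 3, against 6.76 to 6.82 in WCH. Of 20 neuron markers, 8 rose and 1 fell (11 and 1 adjusted over the list alone; relative list median 0.63, camera adjusted p = 0.00499; adjusted p = 0.4 with an estimated correlation). Neuron markers averaged 7.485 in TRAP replicate 2, within the 7.344 to 7.494 of WCH, and 7.786 and 8.107 in TRAP replicates 1 and 3. Translation factor genes had 14 of 42 members higher (15 adjusted over the list alone; relative list median 0.39, camera adjusted p = 0.00109; adjusted p = 0.0783 with an estimated correlation). Cytosolic ribosomal protein genes, whose counts are uncertain because of pseudogenes, had 15 of 68 higher (18 adjusted over the list alone; 0.41, camera adjusted p = 0.000532; adjusted p = 0.489 with an estimated correlation).

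Of 20 oligodendrocyte markers, 12 fell (13 adjusted over the list alone), including Tspan2, the myelin protein gene Mal (log2 fold change −2.13) and Ugt8a (−1.76), an enzyme of myelin lipid synthesis. Their relative list median was −1.46 (camera adjusted p = 9.82e-12; adjusted p = 0.207 with an estimated correlation). Of 20 astrocyte markers, 9 fell (11 adjusted over the list alone; −0.97, camera adjusted p = 6.28e-08; adjusted p = 0.341 with an estimated correlation). Of 20 microglia markers, 7 fell (10 adjusted over the list alone), and P2ry12, a purinergic receptor of microglia, fell by 2.77 on the log2 scale. The list lay −1.14 from the median of all genes (camera adjusted p = 1.14e-07; adjusted p = 0.341 with an estimated correlation). Of 7 mitochondrially encoded mRNAs, 6 fell (7 adjusted over the list alone), such as mt-Nd1 (−3.63) and mt-Co1 (−3.18), subunits of complexes I and IV. Relative to all genes, the list median was −3.51 (camera adjusted p = 1.61e-10; adjusted p = 0.207 with an estimated correlation). The mt-Co1 call was lost when only these groups were fitted (−3.14), and its value was −4.12 without TRAP replicate 3. Of 6 nuclear noncoding RNAs, 2 fell (2 adjusted over the list alone; relative list median −1.13, camera adjusted p = 0.0158; adjusted p = 0.366 with an estimated correlation). The count at the gene Cdr1 (ENSMUSG00000090546) averaged 800 CPM in WCH and 55.3 in TRAP (log2 fold change −3.85, SE 0.656, edgeR adjusted p = 0.00302). It is uncertain which transcript this is, since an antisense RNA covers the same place and the strand setting of the counting is not given. Snap25 (log2 fold change 0.30), Gfap (0.12), Mbp (2.37) and Rpl10a (0.30, at about 1 CPM) did not pass the test.

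In all, 1488 genes were higher and 1459 lower in TRAP (edgeR adjusted p under 0.05), and scaling by total counts, which moved the median of all genes from −0.01 to 0.57, gave 2862 and 231. Without TRAP replicate 3 the counts were 969 and 969, and without WCH replicates 1, 2 or 3 they were 954 and 944, 652 and 832, or 755 and 863. The nuclear RNA Malat1 (−3.86, SE 1.05, edgeR adjusted p = 0.031) lost its call without WCH replicate 1 (−3.76), 2 (−3.70) or 3 (−4.05) or TRAP replicate 1 (−4.09), 2 (−3.55) or 3 (−3.90). The kinase gene Camk2a rose by 1.30 (edgeR adjusted p = 0.019) with overlapping groups and lost its call without WCH replicate 1 (1.32) or 3 (1.2) or TRAP replicate 3 (0.61) and when only these groups were fitted (1.34).

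SNF was compared with WCH to ask which RNAs were richer in the synaptic band than in the whole tissue. In the band, 19 of 20 astrocyte, 14 of 20 oligodendrocyte and 20 of 20 microglia markers and 7 of 7 mitochondrially encoded mRNAs were higher. So were 38 of 46 ion channel genes, with 4 lower, and 32 of 48 endoplasmic reticulum and secretory pathway genes, with 6 lower. None of these list calls held with an estimated correlation (adjusted p = 0.319 to 0.344 with an estimated correlation). Slc1a2 (ENSMUSG00000005089, protein-coding, chromosome 2, 102658659 to 102790784), the main astrocytic glutamate transporter, rose from 2024 ± 238 CPM in WCH to 13650 ± 2370 in SNF (SD, n = 3; log2 fold change 2.75, SE 0.338, edgeR adjusted p = 4.49e-06), and with total counts as the scaling it was 0.39. Itgam (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491), an integrin subunit of microglia, rose from 5.40 ± 0.467 to 55.6 ± 21.5 CPM (log2 fold change 3.36, SE 0.369, edgeR adjusted p = 3.41e-06). The neuronal sodium channel gene Scn8a (ENSMUSG00000023033, chromosome 15, 100869858 to 101045938) rose from 257 ± 13.9 to 946 ± 143 CPM (log2 fold change 1.88, SE 0.236, edgeR adjusted p = 5.61e-06), and with total counts as the scaling it was −0.45.

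All 20 microglia markers rose (20 adjusted over the list alone), among them Itgam and the lysosomal protein gene Cd68 (log2 fold change 2.04). The relative list median was 2.72 (camera adjusted p = 8.53e-15; adjusted p = 0.319 with an estimated correlation). Of 20 astrocyte markers, 19 rose (19 adjusted over the list alone), such as Apoe (2.87), a lipid carrier, and Atp1b2 (2.06), a sodium pump subunit. The list median relative to all genes was 2.12 (camera adjusted p = 1.93e-14; adjusted p = 0.319 with an estimated correlation). Of 20 oligodendrocyte markers, 14 rose (14 adjusted over the list alone), including Mag (2.38), a myelin adhesion protein, and transferrin Trf (2.14). The list lay 1.61 from the median of all genes (camera adjusted p = 2.17e-06; adjusted p = 0.344 with an estimated correlation). Of 12 fibroblast and meninges markers, 11 rose (11 adjusted over the list alone), among them Igfbp2 (2.29) and the proteoglycan Dcn (2.11). Relative to all genes, the list median was 2.54 (camera adjusted p = 1.64e-06; adjusted p = 0.319 with an estimated correlation). Of 46 voltage-gated ion channel genes, 38 rose and 4 fell (39 and 4 adjusted over the list alone), with the calcium channel subunits Cacna2d2 (1.97) and Cacna1i (1.78) beside Scn8a. The list median relative to all genes was 1.45 (camera adjusted p = 2.67e-13; adjusted p = 0.319 with an estimated correlation). Of 48 endoplasmic reticulum and secretory pathway genes, 32 rose and 6 fell (33 and 7 adjusted over the list alone), including the chaperones Calr (2.31) and Hsp90b1 (2.28). The list lay 1.52 from the median of all genes (camera adjusted p = 3.45e-10; adjusted p = 0.319 with an estimated correlation). All 7 tested mitochondrially encoded mRNAs rose (7 adjusted over the list alone; relative list median 3.67, camera adjusted p = 2.91e-06; adjusted p = 0.319 with an estimated correlation). Of 44 postsynaptic density genes, 21 rose and 3 fell (21 and 3 adjusted over the list alone; relative list median 0.97, camera adjusted p = 0.00015; adjusted p = 0.319 with an estimated correlation).

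Neuron markers were split, with 5 higher and 6 lower of 20 (5 and 7 adjusted over the list alone). Their relative median was −0.13, their mean log2 fold change was 0.12, and camera's direction was up with adjusted p = 0.691 (adjusted p = 0.893 with an estimated correlation). Presynaptic vesicle and release genes had 14 members higher and 18 lower of 43 (15 and 18 adjusted over the list alone; camera adjusted p = 0.49; adjusted p = 0.691 with an estimated correlation), with a median of −0.10 and a mean of 0.21. Snap25 (ENSMUSG00000027273, chromosome 2, 136713453 to 136782428), a presynaptic fusion protein, dropped from 7147 ± 376 to 3682 ± 262 CPM (SD, n = 3; log2 fold change −0.96, SE 0.278, edgeR adjusted p = 0.0101), a call lost without WCH replicate 1 (−0.88) or SNF replicate 1 (−0.91). The astrocyte filament gene Gfap rose by 1.36 (edgeR adjusted p = 0.00735), and with total counts as the scaling it was −1.01. The splicing-related gene Rsrp1 (−2.11) and the ubiquitin ligase adaptor Wsb1 (−2.44) fell. Malat1 (−3.60, SE 1.04, edgeR adjusted p = 0.0249) lost its call without WCH replicate 1 (−3.44) or 2 (−3.44) or SNF replicate 1 (−3.25) or 2 (−3.43). Camk2a rose by 1.05 (SE 0.382, edgeR adjusted p = 0.0346), and with total counts as the scaling it was −1.32. Its call was lost without WCH replicate 1 (1.13), 2 (1.19) or 3 (0.94) or SNF replicate 1 (1.06), 2 (1.07) or 3 (1.02). Mbp (1.93), GFP (−0.87) and Rpl10a (0.75) did not pass the test.

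In all, 2757 genes were higher and 2209 lower in SNF (55.5% higher, edgeR adjusted p under 0.05), against 2966 and 1415 with RLE factors (67.7%) and 3072 and 1502 in DESeq2 (67.2%). Total counts as the scaling moved the median of all genes from −0.25 to −2.60 and gave 11 and 11441, so changes here are relative to the bulk of the genes outside the mitochondrial RNA. The count of lower genes was 1238 or 1148 without SNF replicate 1 or 2, and 970, 1353 or 1423 without WCH replicate 1, 2 or 3. The count of higher genes ranged from 2192 to 3003 without each library.

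**Figure D3:**
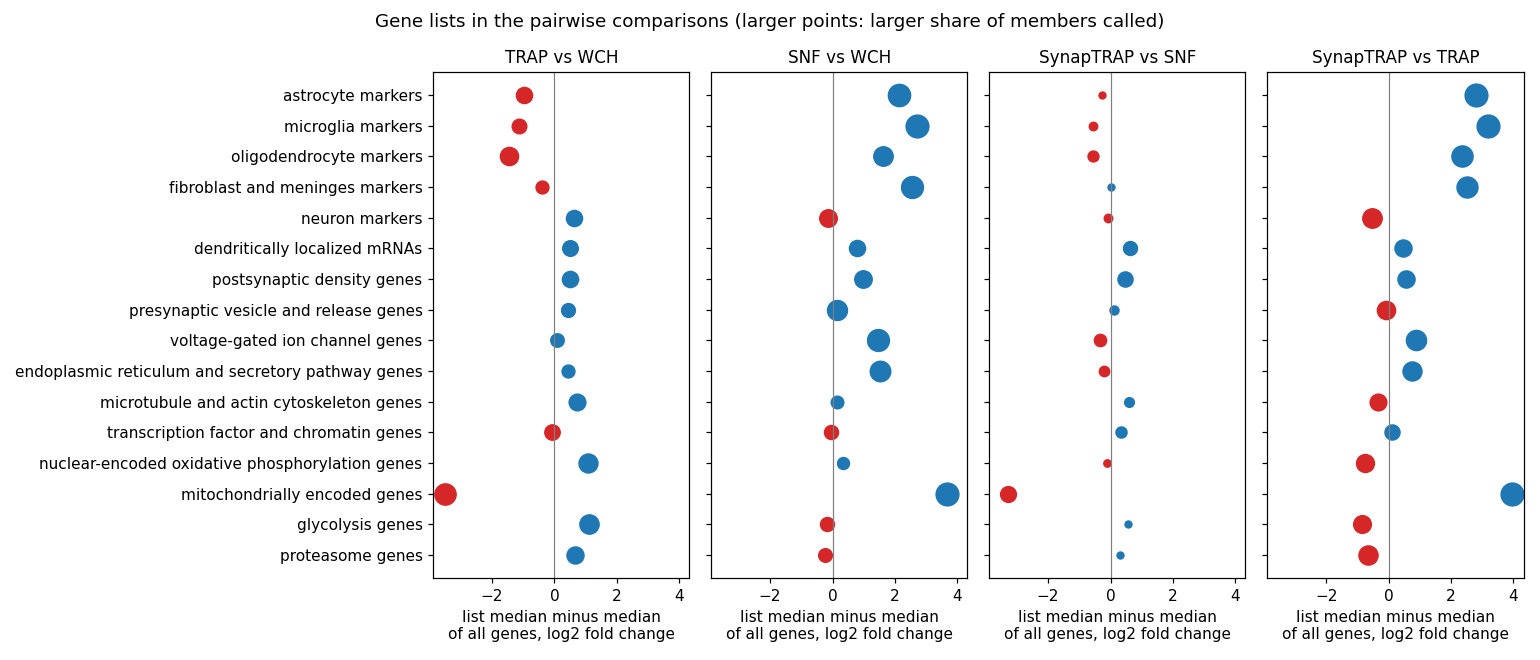
Median log2 fold change of 16 gene lists minus the median of all genes (horizontal axis) in the 4 pairwise contrasts, with blue points above 0, red points below 0 and larger points for a larger share of members called. Glial lists lie below 0 in TRAP against WCH (oligodendrocyte markers −1.46) and above 0 in SNF against WCH (1.61) and SynapTRAP against TRAP (2.35).

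SynapTRAP was compared with SNF to ask which RNAs of the synaptic band were on tagged neuronal ribosomes. After the immunoprecipitation, 9 of 29 dendritically localized mRNAs were higher, and 12 of 44 postsynaptic density genes were higher and 5 lower. Of 7 mitochondrially encoded mRNAs, 3 were lower, and of 46 voltage-gated ion channel genes, 8 were lower and 2 higher. The calls of these 4 lists did not hold with an estimated correlation (adjusted p = 0.129 to 0.613 with an estimated correlation). Dlgap3 (ENSMUSG00000042388, protein-coding, chromosome 4, 127169204 to 127237022), a postsynaptic scaffold protein whose mRNA is dendritic, rose from 55.5 ± 11.2 CPM in SNF to 163 ± 55.4 in SynapTRAP (SD, n = 3; log2 fold change 1.55, SE 0.269, edgeR adjusted p = 0.00554). Kcnab2, a potassium channel subunit, rose from 85.1 ± 13.7 to 223 ± 47.0 CPM (log2 fold change 1.39, SE 0.228, edgeR adjusted p = 0.00417). Cacna2d1 (ENSMUSG00000040118, chromosome 5, 15934691 to 16374511), a calcium channel subunit, was lower at 237 ± 58.8 CPM in SynapTRAP against 586 ± 74.2 in SNF (log2 fold change −1.31, SE 0.241, edgeR adjusted p = 0.00646), and with total counts as the scaling it was 0.65.

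Of 29 dendritically localized mRNAs, 9 rose (13 rose and 2 fell adjusted over the list alone), among them Dlgap3, Shank3 (log2 fold change 1.57), a postsynaptic scaffold protein, and Psd (1.46), an exchange factor of dendrites. The relative list median was 0.63 (camera adjusted p = 3.46e-06; adjusted p = 0.562 with an estimated correlation). The list also rose with immunoprecipitation from the homogenate, where 11 of the 29 were higher and 1 lower in TRAP than in WCH (13 and 3 adjusted over the list alone; relative list median 0.51, camera adjusted p = 0.00125; adjusted p = 0.366 with an estimated correlation). That rise was uneven, with list means of 7.45, 7.17 and 7.96 log2 CPM in TRAP replicates 1 to 3 and 7.02 to 7.12 in WCH. No difference between both immunoprecipitation effects was found for the list (−0.03, camera adjusted p = 0.907; adjusted p = 0.961 with an estimated correlation). The Shank3 and Psd calls were lost without SNF replicate 2 (1.57 and 1.32) or 3 (1.51 and 1.47) or SynapTRAP replicate 1 (1.5 and 1.24). Of 44 postsynaptic density genes, 12 rose and 5 fell (20 and 11 adjusted over the list alone; relative list median 0.45, camera adjusted p = 0.00841; adjusted p = 0.613 with an estimated correlation). In TRAP against WCH, 15 of these rose and 5 fell (20 and 7 adjusted over the list alone; relative list median 0.51, camera adjusted p = 0.00115; adjusted p = 0.366 with an estimated correlation). The difference between both effects was not called for them (−0.18, camera adjusted p = 0.196; adjusted p = 0.735 with an estimated correlation). Of 51 microtubule and actin cytoskeleton genes, 5 rose (12 rose and 1 fell adjusted over the list alone), including the tubulin Tuba1a (1.19), whose call was lost without SNF replicate 2 (1.19) or SynapTRAP replicate 1 (1.03). Relative to all genes, the list median was 0.59 (camera adjusted p = 8.58e-07; adjusted p = 0.613 with an estimated correlation). Of 50 transcription factor and chromatin genes, 8 rose (14 adjusted over the list alone), including the deacetylase Hdac5 (1.57), whose call was lost without SNF replicate 3 (1.47) or SynapTRAP replicate 1 (1.26). The list median relative to all genes was 0.32 (camera adjusted p = 2.22e-05; adjusted p = 0.613 with an estimated correlation). Translation factor genes had 2 of 42 members higher (4 adjusted over the list alone; relative list median 0.34, camera adjusted p = 0.0015; adjusted p = 0.117 with an estimated correlation). Camk2a averaged 2495 ± 94.1 CPM in SNF and 6705 ± 1890 in SynapTRAP (SD, n = 3; log2 fold change 1.43, SE 0.385, edgeR adjusted p = 0.0384). Its call was lost with RLE factors (1.32) and without WCH replicate 1 (1.32), 2 (1.43) or 3 (1.43), TRAP replicate 1 (1.32), SNF replicate 1 (1.42), 2 (1.41) or 3 (1.46), or SynapTRAP replicate 1 (1.37) or 3 (1.19).

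Of 46 voltage-gated ion channel genes, 8 fell and 2 rose (14 and 4 adjusted over the list alone; relative list median −0.33, camera adjusted p = 3.89e-05; adjusted p = 0.613 with an estimated correlation), and camera's direction turned to up with total counts as the scaling. Of 7 mitochondrially encoded mRNAs, 3 fell (7 adjusted over the list alone; relative list median −3.27, camera adjusted p = 1.53e-16; adjusted p = 0.129 with an estimated correlation). Among the lowest single genes were Galnt13 (−1.44), an enzyme that starts mucin-type glycans, Man1a (−1.42), a mannosidase of the Golgi, and Impad1 (−1.49; ENSMUSG00000066324, chromosome 4, 4762484 to 4793355), a Golgi phosphatase, and these fold changes were 0.53, 0.61 and 0.55 with total counts as the scaling. Of 20 oligodendrocyte markers, 3 fell (7 fell and 1 rose adjusted over the list alone; relative list median −0.58, camera adjusted p = 0.00644; adjusted p = 0.745 with an estimated correlation), a list call lost without SNF replicate 2 (−0.26). Of 20 microglia markers, 1 fell (3 adjusted over the list alone; relative list median −0.57, camera adjusted p = 0.000113; adjusted p = 0.613 with an estimated correlation), a list call lost without SynapTRAP replicate 3 (−0.24). No astrocyte marker was called by edgeR (3 fell and 1 rose adjusted over the list alone), and the list lay −0.28 from the median of all genes (camera adjusted p = 0.195; adjusted p = 0.848 with an estimated correlation). GFP rose by 1.48 (SE 0.389, edgeR adjusted p = 0.0336), a call lost without WCH replicate 1 (1.38), SNF replicate 1 (1.41), 2 (1.59) or 3 (1.46) or SynapTRAP replicate 1 (1.35). Gfap (0.88), Mbp (2.34), Snap25 (−0.33) and Rpl10a (−0.18) did not pass the test.

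In all, 307 genes were higher and 240 lower in SynapTRAP (56.1% higher, edgeR adjusted p under 0.05), against 185 and 366 with RLE factors (33.6%), 357 and 634 in DESeq2 (36%) and 12171 and 6 with total counts, which moved the median of all genes from 0.03 to 1.98. The replicate numbers paired these groups, and with the number as a block the counts were 441 and 393, or 942 and 1310 when only these groups were fitted, an alternative chosen after seeing the data. The counts without 1 library were 86 and 64 (SNF replicate 1), 35 and 20 (SNF replicate 2), 24 and 43 (SNF replicate 3), 19 and 43 (SynapTRAP replicate 1), 499 and 453 (SynapTRAP replicate 2), 139 and 261 (WCH replicate 1), 194 and 140 (WCH replicate 2), 214 and 393 (TRAP replicate 1), 281 and 426 (TRAP replicate 2), and 275 and 422 (TRAP replicate 3). Of 31 calls among the named genes, 10 were kept without each library, which include Dlgap3, Kcnab2, Cacna2d1, Galnt13, Man1a and Impad1.

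SynapTRAP was compared with TRAP to ask how the mRNAs on tagged ribosomes differed between the synaptic band and the whole cortex. In SynapTRAP, 20 of 20 astrocyte, 17 of 20 oligodendrocyte and 20 of 20 microglia markers were higher. Lower were 43 of 74 oxidative phosphorylation and 21 of 31 proteasome genes and 8 of 16 glycolysis genes, with 1 of the last higher. None of these list calls held with an estimated correlation (adjusted p = 0.163 to 0.51 with an estimated correlation). Slc1a2 rose from 720 ± 286 CPM in TRAP to 10060 ± 2840 in SynapTRAP (SD, n = 3; log2 fold change 3.81, SE 0.354, edgeR adjusted p = 1.87e-07), and Itgam rose from 2.36 ± 0.882 to 41.9 ± 18.7 CPM (log2 fold change 4.15, SE 0.391, edgeR adjusted p = 3.53e-07). Calm2 (ENSMUSG00000036438, protein-coding, chromosome 17, 87433412 to 87446935), which encodes the calcium sensor calmodulin, dropped from 1262 ± 203 to 278 ± 84.8 CPM (log2 fold change −2.18, SE 0.262, edgeR adjusted p = 2.51e-06). GFP fell by 1.85 on the log2 scale (SE 0.321, edgeR adjusted p = 0.000131; −1.14 without the TRAP and SynapTRAP libraries numbered 3).

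All 20 astrocyte markers rose (20 adjusted over the list alone), including Slc1a3 (log2 fold change 3.67), a further glutamate transporter, and Fgfr3 (2.91), a growth factor receptor. Relative to all genes, the list median was 2.79 (camera adjusted p = 5.61e-25; adjusted p = 0.163 with an estimated correlation). All 20 microglia markers rose (20 adjusted over the list alone), with the purinergic receptors P2ry13 (3.66) and P2ry12 (3.46) among them. The list median relative to all genes was 3.17 (camera adjusted p = 3.56e-20; adjusted p = 0.169 with an estimated correlation). Of 20 oligodendrocyte markers, 17 rose (17 adjusted over the list alone), such as Tspan2 (2.88). The list lay 2.35 from the median of all genes (camera adjusted p = 1.02e-16; adjusted p = 0.163 with an estimated correlation). Of 13 oligodendrocyte precursor markers, 10 rose (11 adjusted over the list alone), including Pdgfra (2.25) and Gpr17 (2.03). Relative to all genes, the list median was 1.93 (camera adjusted p = 1.02e-07; adjusted p = 0.249 with an estimated correlation). Of 12 fibroblast and meninges markers, 10 rose (12 adjusted over the list alone; relative list median 2.5, camera adjusted p = 6.76e-07; adjusted p = 0.266 with an estimated correlation). All 7 tested mitochondrially encoded mRNAs rose (7 adjusted over the list alone; relative list median 3.95, camera adjusted p = 9.07e-07; adjusted p = 0.273 with an estimated correlation). Voltage-gated ion channel genes had 33 members higher and 2 lower of 46 (37 and 3 adjusted over the list alone; relative list median 0.88, camera adjusted p = 3.49e-06; adjusted p = 0.343 with an estimated correlation). Of 44 postsynaptic density genes, 20 rose and 3 fell (20 and 3 adjusted over the list alone; relative list median 0.57, camera adjusted p = 0.00613; adjusted p = 0.38 with an estimated correlation).

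Of 74 nuclear-encoded oxidative phosphorylation genes, 43 fell (46 fell and 1 rose adjusted over the list alone), among them Uqcr10 (log2 fold change −1.73), Ndufa6 (−1.73) and Ndufb7 (−1.51). The relative list median was −0.77 (camera adjusted p = 3.57e-11; adjusted p = 0.242 with an estimated correlation). Of 31 proteasome genes, 21 fell (22 adjusted over the list alone; relative list median −0.66, camera adjusted p = 1.03e-06; adjusted p = 0.301 with an estimated correlation), and of 16 glycolysis genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; relative list median −0.86, camera adjusted p = 0.00244; adjusted p = 0.51 with an estimated correlation). The glycolysis call was lost without the TRAP and SynapTRAP libraries numbered 3 (−0.41). Neuron markers had 5 members higher and 9 lower of 20 (5 and 10 adjusted over the list alone; relative list median −0.52, camera adjusted p = 0.174; adjusted p = 0.664 with an estimated correlation), with Snap25 at 8774 ± 2160 CPM in TRAP and 2938 ± 542 in SynapTRAP (SD, n = 3; log2 fold change −1.58, SE 0.282, edgeR adjusted p = 0.000171). The dendritically localized mRNAs had 13 members higher and 2 lower of 29 (13 and 2 adjusted over the list alone; relative list median 0.45, camera adjusted p = 0.0326; adjusted p = 0.525 with an estimated correlation), a list call lost without TRAP replicate 1 (0.49) or 2 (0.57) or SynapTRAP replicate 3 (0.65). Camk2a rose by 1.18 (edgeR adjusted p = 0.0183) with overlapping groups. Its call was lost when only these groups were fitted (1.24) and without TRAP replicate 1 (1.02) or 2 (0.74) or SynapTRAP replicate 3 (0.93), and the value was 1.86 without TRAP replicate 3. Gfap rose by 2.12 (edgeR adjusted p = 0.000208; 2.74 without TRAP replicate 3), and Mbp (1.90) and Rpl10a (0.28) did not pass the test. In all, 2899 genes were higher and 2432 lower in SynapTRAP (54.4% higher, edgeR adjusted p under 0.05), against 594 and 6403 with total counts as the scaling (8.5%), which moved the median of all genes from −0.02 to −1. The numbers also paired these groups, and with only these groups and the block fitted, an alternative chosen after seeing the data, 1513 genes were lower.

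The difference between both immunoprecipitation effects asks which mRNAs the pull-down changed more in the band than in the homogenate. Oxidative phosphorylation genes lay 1.06 above the median of all genes after immunoprecipitation from the homogenate and −0.12 from it after that from the band (1 of 74 higher in the band; camera adjusted p = 0.401; adjusted p = 0.918 with an estimated correlation). Oligodendrocyte markers lay at −1.46 in the homogenate and −0.58 in the band. Ndufa13 (ENSMUSG00000036199, protein-coding, chromosome 8, 69894180 to 69902558), a complex I subunit, averaged 44.1 and 148 CPM in WCH and TRAP and 87.9 and 71.2 CPM in SNF and SynapTRAP (n = 3 each; difference of log2 fold changes −2.05, SE 0.356, edgeR adjusted p = 0.0119). Ago3 (ENSMUSG00000028842, chromosome 4, 126331704 to 126429556), an Argonaute protein of small RNA pathways, averaged 84.1 and 19.8 CPM in WCH and TRAP and 43.0 and 47.1 CPM in SNF and SynapTRAP (difference 2.21, SE 0.361, edgeR adjusted p = 0.0119). Of 74 nuclear-encoded oxidative phosphorylation genes, 18 were lower in this contrast (44 adjusted over the list alone; relative list median −1.10, camera adjusted p = 1.4e-31; adjusted p = 0.0544 with an estimated correlation). Of 20 oligodendrocyte markers, 2 were higher (9 adjusted over the list alone; relative list median 0.94, camera adjusted p = 3.02e-07; adjusted p = 0.627 with an estimated correlation). In all, 68 genes were higher and 48 lower (58.6% higher, edgeR adjusted p under 0.05), against 38 and 75 with RLE factors (33.6%), 174 and 401 in DESeq2 (30.3%) and 6329 and 0 with total counts (2 genes lower at an unadjusted p under 0.05 in edgeR). No gene was called in edgeR without WCH replicate 2 or SNF replicate 1, where 1016 and 1109 genes were higher and 780 and 877 lower at an unadjusted p under 0.05, and DESeq2 was not run on these subsets. Without 1 library, the counts were 9 and 10 (SNF replicate 2), 14 and 19 (SynapTRAP replicate 1), 241 and 203 (SynapTRAP replicate 2), 112 and 298 (TRAP replicate 1), 9 and 25 (TRAP replicate 2), 6 and 13 (WCH replicate 1) and 10 and 11 (WCH replicate 3). Without WCH replicate 2 the values were −1.93 for Ndufa13 and 2.19 for Ago3, and without SNF replicate 1 they were −1.98 and 2.20.

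The fold changes of separate contrasts were compared across genes, which are not independent replicates. Among the genes that passed the expression filter, the change from homogenate to band was similar with and without immunoprecipitation. Across 13404 genes, SNF against WCH and SynapTRAP against TRAP correlated with a Pearson correlation of 0.667 and a Spearman correlation of 0.667, and of 2991 genes called in both, 2975 moved the same way. TRAP against WCH and SynapTRAP against SNF correlated at r = 0.325 (Spearman 0.332), and all 329 genes called in both moved the same way. Of the 2947 genes called in TRAP against WCH, 2213 (75.1%) had the same sign in SynapTRAP against SNF. Without SNF replicate 3 or SynapTRAP replicate 2 this correlation was 0.172 or 0.2. Without the expression filter the Pearson correlations were 0.329 and 0.094. These pairs share no library. Deviations common to same-numbered SNF and SynapTRAP libraries may raise the first r, and those of TRAP and SynapTRAP the second. How far noise lowers each r was not tested.

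In SynapTRAP, 101 genes were higher than in both SNF and TRAP. They include 6 of the dendritically localized mRNAs (Camk2a, Ddn, Dlgap3, Eef2, Psd and Shank3) and 4 postsynaptic density genes (Begain, Camk2a, Dlgap3 and Shank3), and Ddn, Eef2 and Begain were named after their values were seen. No astrocyte, oligodendrocyte, microglia, oxidative phosphorylation or endoplasmic reticulum gene of the lists is among them by the edgeR calls. Neither is any neuron marker or any presynaptic, voltage-gated ion channel or cytoskeleton gene of the lists. Most of the 101 genes are on none of the lists, so the list members do not describe the overlap as a whole. Among those outside the lists is the actin-bundling gene Lcp1, with log2 fold changes of 2.04 over SNF and 2.24 over TRAP. With 101 of 13404 genes in the overlap, few or no members of such small lists are expected, so these absences say little. Shank3 had log2 fold changes of 1.57 over SNF and 1.32 over TRAP, Dlgap3 1.55 and 1.32, and Psd 1.46 and 1.08. Independent draws of 307 and 2899 genes would share 66.4. Both contrasts use the same 3 SynapTRAP libraries, which were too few to be split, so part or all of the excess may come from them. The overlap was 11 or 203 without SynapTRAP replicate 1 or 2, 34, 17 or 15 without SNF replicate 1, 2 or 3, 58 without WCH replicate 1, 55 without TRAP replicate 1, and 158 with the replicate block.

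**Figure D4:**
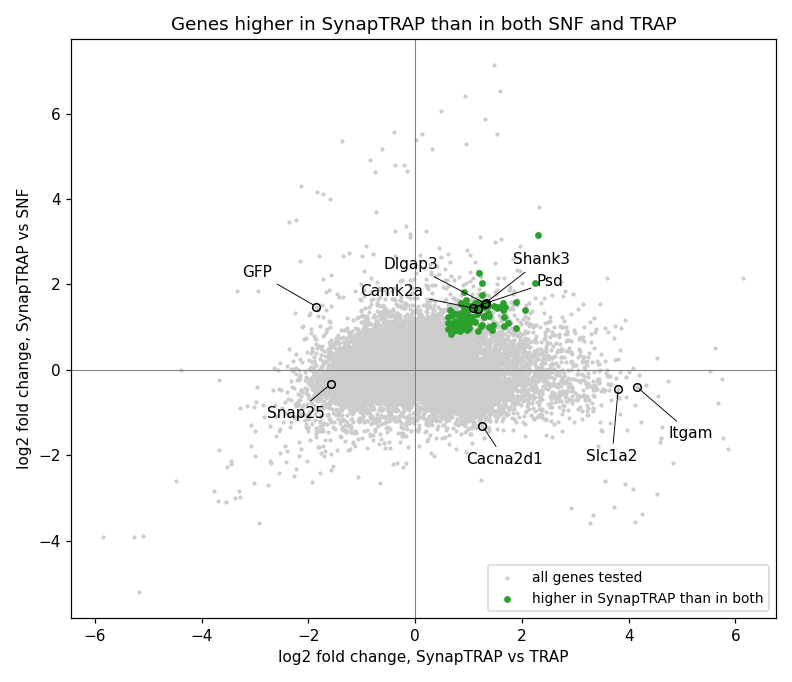
Log2 fold change of SynapTRAP against TRAP (horizontal axis) and against SNF (vertical axis) for 13404 genes (grey), with the 101 genes higher in SynapTRAP than in both in green and named genes circled. Slc1a2 and Itgam lie far right at 3.81 and 4.15 with little change on the vertical axis, and Dlgap3, Shank3, Psd and Camk2a lie in the green group.

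The authors' deposited tables list genes chosen on these same libraries, so counts of them here are not independent evidence. Of 109 genes in the authors' deposited table of local candidates, 62 were called higher in SynapTRAP than in SNF, 86 higher in SynapTRAP than in TRAP, 58 higher in SNF than in WCH and 61 higher in TRAP than in WCH. That table holds 7 of the dendritically localized mRNAs, which are Arc, Camk2a, Ddn, Dlgap3, Eef2, Psd and Shank3 (Arc is named here as a member, not by the rule). It also holds the astrocyte markers Acsbg1 and Aldh1l1, the fibroblast marker Col1a1 and the oligodendrocyte precursor marker Bcas1, of which Acsbg1, Aldh1l1 and Bcas1 are likewise not named by the rule. Of 275 genes in the authors' deposited table of somatic candidates, 117 were called higher in TRAP than in WCH, 212 lower in SNF than in WCH, 246 lower in SynapTRAP than in TRAP and 16 higher in SynapTRAP than in SNF. Of 3508 genes in the authors' deposited table of genes enriched in the band, 3441 were tested here and 2740 called higher in SNF than in WCH. It lists all 20 microglia markers, all 20 astrocyte markers and 39 voltage-gated ion channel genes. The unadjusted p-values in the authors' deposited tables reach 0.0496, 0.0499 and 0.05, and 22, 206 and 3179 genes have a false discovery rate under 0.05 there. The local and somatic tables do not state the contrast behind each column, and it was taken from the closest contrast of the counts. The correlations that follow come in part from that matching. Fold changes correlated across genes with those in the authors' deposited tables with r = 0.75 for SynapTRAP against SNF and 0.961 for SNF against WCH in the local table, 1 for TRAP against WCH and 0.709 for SNF against WCH in the somatic table, and 0.972 for SNF against WCH in the band table. The count of local candidates higher in SynapTRAP than in SNF was 7 without SynapTRAP replicate 1 and 29, 12 or 9 without SNF replicate 1, 2 or 3. Their count in SNF against WCH was 30 without SNF replicate 1 and 38 or 31 without WCH replicate 2 or 3, and in TRAP against WCH it was 36 without WCH replicate 3 and 37 without TRAP replicate 3. Somatic candidates higher in TRAP numbered 67, 33 or 48 without WCH replicate 1, 2 or 3, and those lower in SNF 121 or 126 without SNF replicate 1 or 2 and 69 without WCH replicate 1. Somatic candidates higher in SynapTRAP than in SNF numbered 3, 7 or 8 without WCH replicate 1, 2 or 3 and 9, 8 or 8 without TRAP replicate 1, 2 or 3. They numbered 1 without SNF replicate 1, and edgeR called none without SNF replicate 2 or 3 or SynapTRAP replicate 1.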

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

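The tests chosen only after the result was seen are those of band RNA carried through the immunoprecipitation, of an equal loss of glial RNA, of mitochondria that came down with the ribosomes, and the other splits of the samples. Length and GC content were tests set before.

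The effect of the immunoprecipitation differed between the band and the homogenate by a test of that difference (edgeR adjusted p under 0.05), with 68 genes higher and 48 lower. Among the named genes, oxidative phosphorylation subunits had a lower effect in the band, with differences of log2 fold changes of −2.05 for Ndufa13, −1.98 for Uqcr11, −1.84 for Uqcr10, −1.66 for Ndufa6 and −1.51 for Ndufb7. Oligodendrocyte genes had a higher effect in the band, with 2.4 for Ermn and 1.67 for Tspan2, and Tmem88b had 1.98. The other higher ones were Efhd1 (2.45), Dusp11 (2.39), Snap23 (2.30) and Ago3 (2.21). The other lower ones were Romo1 (−2.10), Nop10 (−2.08), Yipf3 (−2.08), Ttc9b (−2.02), Fbll1 (−2.02), Kalrn (−1.80) and Bex3 (−1.39). The rule named 10 genes for this contrast, which are Efhd1, Ermn, Dusp11, Snap23, Ago3, Ttc9b, Ndufa13, Yipf3, Nop10 and Romo1. All 10 lost their call without WCH replicate 2 and also without SNF replicate 1. In that order, the values were 2.38, 2.32, 2.28, 2.06, 2.19, −1.96, −1.93, −2.01, −1.87 and −1.92 without WCH replicate 2. They were 2.85, 2.44, 2.43, 2.48, 2.20, −1.75, −1.98, −2.11, −1.98 and −2.01 without SNF replicate 1.

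Lists differed in the same test of the difference by camera at the preset correlation, and no such call held with an estimated correlation (smallest adjusted p = 0.0544, for oxidative phosphorylation). Relative to all genes, the medians were 0.937 for oligodendrocyte, 0.934 for astrocyte, 0.673 for microglia and 0.271 for oligodendrocyte precursor markers and 0.227 for transcription factor and chromatin genes. They were −1.102 for oxidative phosphorylation, −0.603 for neuron markers, −0.582 for glycolysis, −0.561 for endoplasmic reticulum, −0.559 for cytosolic ribosomal protein, −0.499 for cytoskeleton, −0.465 for ion channel and −0.356 for proteasome genes. The cytoskeleton call was lost with the block (−0.49), without TRAP replicate 1 (−0.51) or 3 (−0.10), without SNF replicate 3 (−0.59) and without SynapTRAP replicate 3 (−0.31). The glycolysis call was lost without TRAP replicate 1 (−0.57) or 3 (−0.44), SNF replicate 1 (−0.47) or SynapTRAP replicate 3 (−0.33). The proteasome call was lost without SynapTRAP replicate 3 (−0.21). The microglia call was lost without TRAP replicate 2 (0.43), SNF replicate 3 (0.35) or SynapTRAP replicate 1 (0.42), and that of oligodendrocyte precursors without TRAP replicate 2 (−0.08).

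A signal outside the gene counts was the share of reads that were not aligned. It was 11.8% in TRAP replicate 2 and 9.43% in SynapTRAP replicate 2, against at most 2.62% in the WCH libraries.

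Glial markers were higher in SynapTRAP than in TRAP, with relative list medians of 2.79 for astrocyte, 2.35 for oligodendrocyte and 3.17 for microglia markers (adjusted p = 0.163 to 0.169 with an estimated correlation). An even carry-over of all band RNA with its mitochondrial RNA is argued against, since mitochondrially encoded mRNAs lay −2.79 log2 units from the glial median between SNF and SynapTRAP. Glial RNA richer in the band with an equal loss in both immunoprecipitations is also argued against, since the gain of the neuron over the astrocyte score was smaller in the band by a difference of −1.3 (permutation p = 0.01 over 400 labelings; −1.48 and −1.09 with permutation p = 0.005 and 0.02 against oligodendrocyte and microglia markers; permutation p = 0.0125 for each over 160 labelings that turn SNF and SynapTRAP only within pairs, the smallest they can give). An even carry-over of band RNA outside the mitochondria cannot be told apart from other sources, since 57 of 11595 such genes lay below the glial median in SynapTRAP against SNF at an adjusted p under 0.05 in the fit with the replicate block (483 at an unadjusted p under 0.05) and 0 of 13383 by edgeR in the fit of all groups (326 at an unadjusted p under 0.05), where it predicts none in either and the bound against it in the blocked fit, set after the result was seen, was 100. No biological explanation was tested, since the design holds no group for it.

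Nuclear-encoded oxidative phosphorylation genes were higher in TRAP than in WCH, with a list median of 1.05. The list lay at percentile 100 of 10000 random lists matched on transcript length. The median of those lists was 0.36, with 95% of them between 0.093 and 0.568. Matched on GC content, it also lay at percentile 100, with a matched median of 0.07. Random genes of the same length or GC content thus typically rose less than the list. The random lists were drawn gene by gene, so the percentiles leave out the correlation between members, estimated at 0.145. Length and GC content were also matched separately, so a part of both together is not excluded. Mitochondria that came down with the ribosomes are argued against by the mitochondrially encoded mRNAs, whose median was −3.525. More of these mRNAs on neuronal ribosomes than in the whole tissue remains a hypothesis, found and examined on the same data, and the list call did not hold with an estimated correlation (adjusted p = 0.0783).

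Dendritically localized mRNAs were higher in SynapTRAP than in SNF, with a list median of 0.65. They were also higher in TRAP than in WCH (relative list median 0.51), but unevenly over the TRAP libraries. No difference between both effects was found (−0.03, camera adjusted p = 0.907; adjusted p = 0.961 with an estimated correlation). The list lay at percentile 100 of 10000 random lists matched on transcript length (matched median 0.05). Matched on GC content, it lay at percentile 99.99 (matched median 0.09). In the fit of only these groups with the replicate block, this was percentile 100, with a list median of 0.57. Random genes of the same length or GC content thus typically rose less than the list. The random lists were drawn gene by gene, so the percentiles leave out the correlation between members, estimated at 0.203. Length and GC content were also matched separately, so a part of both together is not excluded. Other technical differences between SNF and SynapTRAP libraries, such as the mitochondrial share, stay open, and the list call did not hold with an estimated correlation (adjusted p = 0.562).

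With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts of called genes and the highest of the other splits were 2947 and 0 for TRAP against WCH, 4966 and 0 for SNF against WCH, 547 and 16 for SynapTRAP against SNF, and 5331 and 0 for SynapTRAP against TRAP, each as large in 1 split. For called lists these were 16 and 18 (3 splits as large), 18 and 17 (1), 13 and 15 (4) and 16 and 14 (1). In the paired groups, the other splits that part all 3 pairs gave at most 0 called genes. For the difference between immunoprecipitation effects, 5 of 60 drawn splits, the real grouping included, gave as many genes as the real 116, with a highest of 1273. For lists, 21 of 60, the real grouping included, gave as many as the real 13, with a highest of 19. By these shares chance was not excluded for either count. All 4 other splits with as many genes kept the real grouping of the TRAP and WCH libraries, so the effect of TRAP against WCH enters them. In edgeR, none of the 51 splits that kept neither the real grouping of TRAP and WCH nor that of SynapTRAP and SNF had a called gene. Such mixed splits put the differences between preparations into the spread within groups, so few or no calls are likely whatever the cause. The same holds for the other splits of 3 libraries against 3, so these low counts do not decide the question of chance.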

How the results depend on the processing

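The tests chosen only after the data were seen are those with only the groups compared and the replicate block together, and those without the TRAP and SynapTRAP libraries numbered 3. The cause of a change was not tested except where the alternative itself gives it. Among the named genes, 25 of 34 calls in TRAP against WCH, 28 of 36 in SNF against WCH, 10 of 31 in SynapTRAP against SNF, 34 of 35 in SynapTRAP against TRAP and 0 of 10 in the difference between immunoprecipitation effects (all by edgeR) were kept without each library. The SNF libraries had only 1819853 to 2111322 counts outside the mitochondrial genome, and how far this limits contrasts that use them was not tested. The replicate numbers paired SynapTRAP with SNF and with TRAP. In SynapTRAP against SNF the replicate block ended the call of the actin-bundling gene Lcp1 (2.07), made a call of the nuclear noncoding RNA list (−0.67) and changed no other named call in the paired groups. For WCH with TRAP and with SNF, which were not treated as paired (correlations −0.015 to 0.165), the block ended the calls of Sptb (2.48), Mapk8ip2 (2.59) and Dbn1 (2.47) in TRAP against WCH. It ended those of Col1a1 (3.20) and Col1a2 (3.01) in SNF against WCH and of the cytoskeleton list in the difference between immunoprecipitation effects (−0.49). With the replicate block, 393 genes were lower in SynapTRAP than in SNF and 217 and 149 were higher and lower in the difference between effects. With it, 158 were higher in SynapTRAP than in both SNF and TRAP. The blocked fit called 2919 of the 2947 genes of TRAP against WCH, 4944 of 4966, 546 of 547, 5276 of 5331 and 116 of 116 in the order of contrasts.

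RLE factors gave 1415 genes lower in SNF against WCH, 185 higher and 366 lower in SynapTRAP against SNF, and 38 higher and 75 lower in the difference between effects. With them, 139 somatic candidates were lower in SNF than in WCH and 7 higher in SynapTRAP than in SNF. Total counts as the scaling moved the medians of all genes to 0.57, −2.60, 1.98, −1 and 1.46, which by itself turns calls. They gave 2862 higher and 231 lower genes in TRAP against WCH, and 11 and 11441 in SNF against WCH. They gave 12171 and 6 in SynapTRAP against SNF, 594 and 6403 in SynapTRAP against TRAP, and 542 genes higher in SynapTRAP than in both. The difference between effects had 6329 and 0 (edgeR, 2 lower at an unadjusted p under 0.05, and 401 by DESeq2 with its own factors). With total counts, 109 local candidates were called higher in SynapTRAP against SNF, 17 in SynapTRAP against TRAP and 0 in SNF against WCH by edgeR. Of the somatic candidates, 259 were called higher in TRAP against WCH and 275 in SynapTRAP against SNF, and 6 genes of the band table were higher in SNF. The fold changes that total counts reversed in SNF against WCH were Calr −0.02, Igfbp2 −0.038, Hsp90b1 −0.033, Enpp2 −0.145, P4hb −0.184, Trf −0.241, Dcn −0.174, Atp1b2 −0.293, Cd68 −0.323, Cacna2d2 −0.407, Scn8a −0.452, Cacna1i −0.579, Gfap −1.013 and Camk2a −1.317. In SynapTRAP against SNF they were Scn8a 1.025, Cacna2d1 0.648, Dpy19l4 0.667, Derl2 0.608, Man1a 0.607, Galnt13 0.526, Suco 0.41, Impad1 0.553, Fam57a 0.529 and Xk 0.535. Camera's direction turned there for the endoplasmic reticulum (relative median −0.171) and ion channel lists (−0.285).

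No expression filter gave 547 higher genes in SynapTRAP against SNF, 310 and 202 in the difference between effects, and 192 higher in SynapTRAP than in both. It gave correlations of 0.329 (SNF against WCH with SynapTRAP against TRAP) and 0.094 (TRAP against WCH with SynapTRAP against SNF), with more genes of few counts included. A minimum of 5 CPM in 3 libraries gave 0.739 and 0.438. DESeq2 gave 634 lower genes in SynapTRAP against SNF and 174 and 401 in the difference between effects. Only the groups compared gave 140 and 121 in SynapTRAP against SNF and 1458 lower in SynapTRAP against TRAP, with fewer libraries in the fit. With the replicate block added these were 942 and 1310, and 1513. This setting was not run for the difference between effects, which needs all 4 groups. Leaving out both libraries numbered 3 gave 540 and 385 in SynapTRAP against SNF, and 120 and 90 in the difference between effects. It gave a correlation of 0.392 for TRAP against WCH with SynapTRAP against SNF, 29 somatic candidates higher in SynapTRAP than in SNF and a cytoskeleton median of −0.009 in the difference between effects, where camera's direction turned. Leaving out the mitochondrially encoded genes moved none of the counts of called genes by over 1.5 times.

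Over the 12 fits that each left out 1 library, the counts of higher and lower genes were 652 to 1800 and 832 to 1826 in TRAP against WCH and 2192 to 3003 and 970 to 2633 in SNF against WCH. They were 19 to 499 and 20 to 453 in SynapTRAP against SNF, 2324 to 2971 and 1953 to 2642 in SynapTRAP against TRAP, and 0 to 241 and 0 to 298 in the difference between effects. The 0 was found by edgeR without WCH replicate 2, with 1016 and 780 at an unadjusted p under 0.05, and without SNF replicate 1, with 1109 and 877. No other tool was run there. Correlations ranged from 0.559 to 0.685 and from 0.172 to 0.4, and genes higher than in both from 11 to 203. Local candidates ranged from 7 to 66 (SynapTRAP against SNF), 66 to 89 (SynapTRAP against TRAP), 30 to 77 (SNF against WCH) and 36 to 75 (TRAP against WCH). Somatic candidates ranged from 33 to 154 (higher in TRAP) and 69 to 233 (lower in SNF). They ranged from 238 to 246 (lower in SynapTRAP than in TRAP) and 0 to 22 (higher in SynapTRAP than in SNF), and genes of the band table from 2173 to 2946.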

Other observations

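The tests of GC content across all genes were chosen only after the data were seen. Further gene groups changed between the preparations. Genes of cholesterol synthesis had 13 of 22 members higher in SNF than in WCH (13 adjusted over the list alone; relative list median 1.41, camera adjusted p = 1.25e-05; adjusted p = 0.319 with an estimated correlation). In the immunoprecipitates, 12 were higher and 1 lower in SynapTRAP than in TRAP (12 and 1 adjusted over the list alone; 0.97, camera adjusted p = 0.000207; adjusted p = 0.301 with an estimated correlation). Immediate early genes, which respond to neuronal activity, had 9 lower and 2 higher of 24 in SNF than in WCH (10 and 2 adjusted over the list alone; −0.46, camera adjusted p = 0.0346; adjusted p = 0.459 with an estimated correlation), a list call lost without WCH replicate 2 (−0.45) or SNF replicate 1 (−0.49) or 3 (−0.29). In SynapTRAP against TRAP, 7 of them were lower (5 adjusted over the list alone; −0.62, camera adjusted p = 0.0137; adjusted p = 0.343 with an estimated correlation). Presynaptic genes had 11 higher and 2 lower of 43 in TRAP than in WCH (12 and 2 adjusted over the list alone; 0.43, camera adjusted p = 0.00508; adjusted p = 0.341 with an estimated correlation).

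Inhibitory neuron markers had 9 higher and 2 lower of 19 in SNF than in WCH (9 and 3 adjusted over the list alone; 1.34, camera adjusted p = 0.0251; adjusted p = 0.55 with an estimated correlation), a list call lost without SNF replicate 2 (1.23). Excitatory neuron markers had 7 higher and 5 lower of 18 there (7 and 5 adjusted over the list alone; camera adjusted p = 0.77; adjusted p = 0.842 with an estimated correlation), with a median of −0.23 and a mean of 0.12. Endothelial markers had 5 of 16 higher (5 adjusted over the list alone; 1.67, camera adjusted p = 0.0251; adjusted p = 0.55 with an estimated correlation). Mural cell markers had 4 of 10 higher (5 adjusted over the list alone; 1.82, camera adjusted p = 0.02; adjusted p = 0.459 with an estimated correlation). The mural call was lost with a minimum of 5 CPM in 3 libraries (0.78). Choroid plexus and ependyma markers had 4 of 8 higher (4 adjusted over the list alone; camera adjusted p = 0.291; adjusted p = 0.636 with an estimated correlation). Blood cell markers had 1 higher and 1 lower of 7 (1 and 1 adjusted over the list alone; camera adjusted p = 0.378; adjusted p = 0.58 with an estimated correlation). Hippocampus markers had 4 higher and 1 lower of 10 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0723; adjusted p = 0.459 with an estimated correlation). Striatum markers had 4 higher and 3 lower of 11 (4 and 3 adjusted over the list alone; camera adjusted p = 0.987; adjusted p = 0.994 with an estimated correlation).

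Across 13306 genes with a GENCODE M21 transcript, the log2 fold change of TRAP against WCH went with GC content (Spearman 0.565 across genes, which are not independent replicates). Genes higher in TRAP had a median GC content of 56.1% and genes lower 43.4%, against 50% over all genes. The same correlation was 0.192 for SNF against WCH, 0.298 for SynapTRAP against SNF, −0.065 for SynapTRAP against TRAP and −0.309 for the difference between immunoprecipitation effects. The genes called in SynapTRAP against SNF also differed widely, with a median GC content of 57.3% for higher and 42.9% for lower genes. These medians were 50.9% and 46.6% in SNF against WCH, 49.4% and 51.1% in SynapTRAP against TRAP, and 44.7% and 55.9% in the difference between effects. Genes higher in TRAP than in WCH also had shorter transcripts, with a median of 2537 bases against 4656 for lower genes and 3311 over all genes. Genes higher in SynapTRAP than in TRAP had longer ones, with 4176 against 2413 bases.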
